A study of Mus musculus and Homo sapiens with 36 samples.

How the data were processed

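Of the 36 samples of the series, in 15 groups, those of the CPSF6 HITS-CLIP groups were analysed, wild-type and Mbnl1/2 KO MEFs with 2 libraries each per the labels. The other 32 samples (PolyA-seq of mouse MEFs, mouse quadriceps and human muscle, and HITS-CLIP of Mbnl1, Mbnl2 and Mbnl3) were not analysed here. The deposited unit was signal, the whole-number coverage of each nucleotide by tags, in separate plus-strand and minus-strand tracks, pooled by the authors over the libraries of a genotype and not scaled for depth. Per the method description deposited with the series, CLIP reads were filtered on quality, aligned to mm9 with Novoalign, and reduced to unique tags by their mapping start and a random barcode. Removal by barcode can leave more than 2 tags at a position, yet no start position in either profile carried more. Exactly 2 tags were found at 70632 wild-type and 139008 KO start positions and more than 2 at 0, which argues against removal by barcode alone. The sources used here do not state whether tags were instead reduced by position alone within each of 2 libraries. In that case a position with 2 tags holds 1 from each library and the height of an island is limited by the tag length. A second deposited description names BWA or Novoalign. The submitters' processing notes also name SAMtools and bedtools and the builds mm10 and hg19, and versions are not given in the sources used here. Library preparations of the pooled libraries cannot be separated in the profiles, and leftover duplicates or tags that reached more than 1 library would narrow the counting intervals wrongly.

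The planned analysis per gene, by annotated feature, around annotated 3′ ends, within 3′ UTRs, by sequence motif, by gene list and by cell type marker needed an annotation or sequence of mm9. The annotation at hand was of GRCm38, coordinates were not converted, and these analyses were not run, so that no gene is named and Mbnl1, Mbnl2 and Cpsf6 themselves could not be located. Islands took the place of genes: covered stretches of 1 strand with a height of at least 10 in either profile, merged within 50 nt. Windows of 50 kb and 1 Mb, pairs of islands at most 5 kb apart, chromosomes and start positions were added after the data were seen. Tag equivalents are the summed coverage over the mean length of isolated tags, which were covered stretches of height 1 and at most 40 nt. The planned depth scale over protein-coding exons was replaced by total coverage (1.3175 KO over wild type). Log2 ratios were taken on tag equivalents with a pseudocount of 1 per profile, for regions with at least 50 tag equivalents over both profiles, with exact Clopper-Pearson 95% intervals of the ratio. A region was called by size alone, at 2-fold. The number called by counting error was simulated by binomial draws of each region's tags at the median ratio. A floor of 3 counts equals 0.000508% of the wild-type and 0.000386% of the KO tags.

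Start positions were read from the steps of the profiles at the 5′ end of tags; those sharing a stretch with no other start were called isolated. The islands named are, by the rule fixed beforehand, taken from the 10 highest and 10 lowest ratios among those past 2-fold and the 10 with most coverage. Runs of adjacent called windows are named from the 8 highest and 8 lowest ratios and those of at least 250 kb, and the island arrays and the pair with the largest shift were chosen after their values were seen. The alternatives were the depth scale, a cap on the top 0.1% of covered positions, the minimum of tags, the pseudocount, strand, the fold, the island height and overlap, the window length, start positions counted once and shared start positions left out. The steps were tested on simulated data. From a simulated profile of 40000 thinly spread start positions and tags of equal length, 99.5% of start positions came back with their tags. Recovery in densely filled islands was not tested. Among the 7249 windows with real totals, 96.0% of those changed 3-fold and 62.0% of those changed 2-fold were called, against 0.40% of the unchanged ones, and among the 247 islands 91.7% of those changed 3-fold and 46.2% of those changed 2-fold. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.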

Results

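The series examined how the muscleblind-like RNA-binding proteins (Mbnl1, Mbnl2 and Mbnl3), which are sequestered in myotonic dystrophy, affect the choice of poly(A) sites. The part analysed here is the binding of CPSF6, a subunit of the cleavage factor I complex that takes part in poly(A) site choice, in mouse embryonic fibroblasts (MEFs). CPSF6 binding was measured by HITS-CLIP, in which ultraviolet light crosslinks a protein to the RNA it touches and the RNA fragments recovered with the protein are sequenced as tags. Wild-type MEFs were compared with MEFs lacking Mbnl1 and Mbnl2 (Mbnl1/2 KO). The labels list 2 CPSF6 libraries per genotype, whereas the series text gives 3, and each genotype was represented by 1 pooled, strand-specific coverage profile in mm9 coordinates. No replicate error could therefore be computed, no p-value is given, and every interval covers counting error only. The wild-type profile held 590541 tag equivalents (summed coverage divided by the mean tag length of 35.13 nt) and the Mbnl1/2 KO profile 778015, so that 1.3175 KO tags stood for each wild-type tag. The wild-type tags covered 15864787 nt and the KO tags 19308329 nt. Regions are given by position, since no mm9 annotation was used here. No measure of RNA level was used either, so a difference in coverage cannot separate a change in CPSF6 binding from a change in RNA amount.

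Most CPSF6 tags lay scattered over the genome, and a small share was gathered in strong islands. Covered stretches reaching a height of 10 tags held 5.3% of the coverage in wild-type MEFs and 4.2% in Mbnl1/2 KO MEFs. The strongest island lay on the plus strand of chromosome 17 (39982386 to 39985775), with 2336.4 tag equivalents in wild type, 2301.0 in KO and heights of 73 and 72. It was followed by an island on the minus strand of chromosome 19 (5795962 to 5799989), with 1177.4 and 1614.2 tag equivalents, and by the first 2751 nt of the mitochondrial genome on the plus strand, with 765.2 and 1170.6. An island on the plus strand of chromosome 6 (3150766 to 3151677) held 644.8 and 635.4 tag equivalents. The minus strand of chromosome 8 carried a regular array of 47 islands between 126062686 and 126145946, with a median width of 122 nt and a median spacing of 1696 nt. A smaller array of 8 islands lay on the minus strand of chromosome 6 (47600761 to 47631057) at a median spacing of 4326 nt.

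The first comparison asked whether loss of Mbnl1 and Mbnl2 changed CPSF6 coverage from region to region, with islands in the place of genes. Relative to total coverage, strong islands were lower in Mbnl1/2 KO MEFs as a group: 220 of the 247 islands with at least 50 tag equivalents had a ratio below 1, and the median log2 ratio was -0.59, a ratio of 0.66. The 47 islands of the chromosome 8 array were all below 1, and their summed coverage in KO was 0.58 of that in wild type. Given their regular spacing, these 47 islands may not be independent loci. Without them, 200 islands were left, with a median log2 ratio of -0.53, of which 2 were at least 2-fold higher and 17 at least 2-fold lower. Islands with a height of 20 to 39 had a median log2 ratio of -0.66, those of 10 to 19 of -0.21 and those of 40 or more of -0.61. The split turned when the median island was taken as unchanged: scaling to the median ratio left 11 islands at least 2-fold higher and 2 at least 2-fold lower, in place of 2 and 25. Counting error alone, with every island at the median ratio, gave a mean of 18.8 islands at least 2-fold lower and 0.0 higher, so that the common shift with counting error accounted for most of the 25 lower islands in number.

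The pair of islands that were at least 2-fold higher in KO lay side by side on the plus strand of chromosome 6. The first (4489470 to 4489714) held 14.0 tag equivalents in wild type and 49.0 in KO, a ratio of 2.57 (95% interval 1.44 to 5.21), and the second (4490522 to 4491026) held 23.0 and 71.4, a ratio of 2.32 (1.45 to 3.93). With each start position counted once, 160 islands reached the minimum of tags, of which 0 were at least 2-fold higher and 4 were lower. The log2 ratios of the chromosome 6 pair were then 0.95 and 0.99, just under 2-fold. The lowest ratios among the lower islands were 0.32 (0.16 to 0.55) on the plus strand of chromosome 15 (82980081 to 82980226) and 0.33 (0.19 to 0.54) on the minus strand of chromosome 1 (115800563 to 115800859). An island on the minus strand of chromosome 12 (55820144 to 55820313) fell from 107.2 to 58.1 tag equivalents, a ratio of 0.42 (0.29 to 0.57), but its log2 ratio of -1.27 fell short of 2-fold on the median scale (-0.66), with capped coverage (-0.94) and with starts counted once (-0.72). An island in the chromosome 8 array (126064424 to 126064511) had a ratio of 0.38 (0.21 to 0.65). Its log2 ratio of -1.39 also fell short of 2-fold on the median scale (-0.79) and with starts counted once (-0.90). Of the strongest islands, the chromosome 17 island had a log2 ratio of -0.42 (-0.50 to -0.34) on total coverage and of 0.19 on the median scale, where its direction flips. With capped coverage the log2 ratio was -0.64. Its peak, with heights of 73 and 72, lies at what 2 tags per start position allow, which limits the ratio at the peak. A second island of that locus (39979942 to 39982296) stayed lower on both scales, at -1.05 (-1.23 to -0.87) and -0.44. The chromosome 19 island stood at 0.06 (-0.05 to 0.17) on total coverage, 0.67 on the median scale and -0.12 with capped coverage, and the mitochondrial island at 0.22 (0.08 to 0.35), 0.82 and 0.00.

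**Figure D1:**
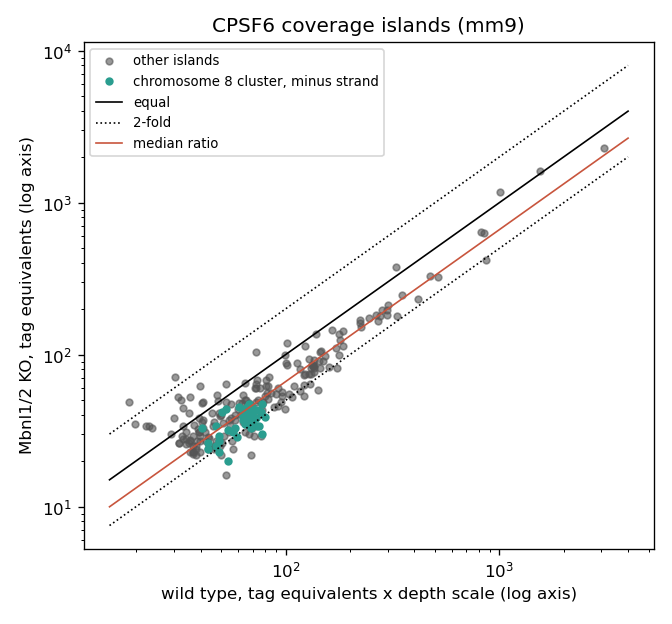
Tag equivalents per island in Mbnl1/2 KO (y axis) against wild type multiplied by the depth scale (x axis), both on log axes, for the 247 islands with at least 50 tag equivalents; each point is 1 island. Most points, among them all 47 of the chromosome 8 array, lie below the line of equal coverage, around the median ratio of 0.66.

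The comparison of islands present in 1 genotype only gave no direction that held. At a height of 10 in both profiles, 638 of the 907 wild-type islands overlapped a KO island and 269 did not, while 430 of the 1069 KO islands overlapped none in wild type. With KO heights scaled down to the wild-type total, 504 islands were present only in wild type and 61 only in KO. No pair of neighbouring islands shifted by 2-fold: of 75 pairs on 1 strand at most 5 kb apart, 37 had more of their coverage in the downstream island in KO and 38 in the upstream island, 0 by at least 2-fold. Of these pairs, 46 lay within the chromosome 8 array and some others within the chromosome 6 array. Among the 29 pairs outside the chromosome 8 array, the numbers were 16 and 13. The largest shift was on the plus strand of chromosome 16, where the downstream island (37834865 to 37835170) gained 1.89-fold over the upstream island (37834193 to 37834597).

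Larger differences appeared among windows of 50 kb, which sum all coverage of a strand, islands included, and far outnumber the 247 tested islands. Some of these differences lay in long stretches of 1 strand. Among 7249 windows of 50 kb with at least 50 tag equivalents on a strand, a division chosen after the data were seen, 310 were at least 2-fold higher in Mbnl1/2 KO MEFs and 242 at least 2-fold lower. Counting error with every window at the median ratio gave means of 43.4 and 3.4. The median log2 ratio was 0.12, and scaling to the median ratio gave 224 higher and 334 lower windows. With adjacent windows joined, there were 253 higher runs and 188 lower runs, of which 30 and 30 held at least 2 windows; the others were single windows of 50 kb. The longest higher run covered 650 kb of the minus strand of chromosome 8 (49300001 to 49950000), with 189.0 tag equivalents in wild type and 1393.7 in KO, a ratio of 5.58 (4.81 to 6.55), while the plus strand there had 10.0 and 22.0. Of the 175 wild-type start positions in this run, 144 (82.3%, 75.8 to 87.6) were also KO start positions, so the interval does not cover tags present in both profiles. The longest lower run covered 550 kb of the minus strand of chromosome 3 (29900001 to 30450000), with 989.1 and 419.7 tag equivalents, a ratio of 0.32 (0.29 to 0.36), and 137 of its 353 KO start positions were also wild-type start positions.

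**Figure D2:**
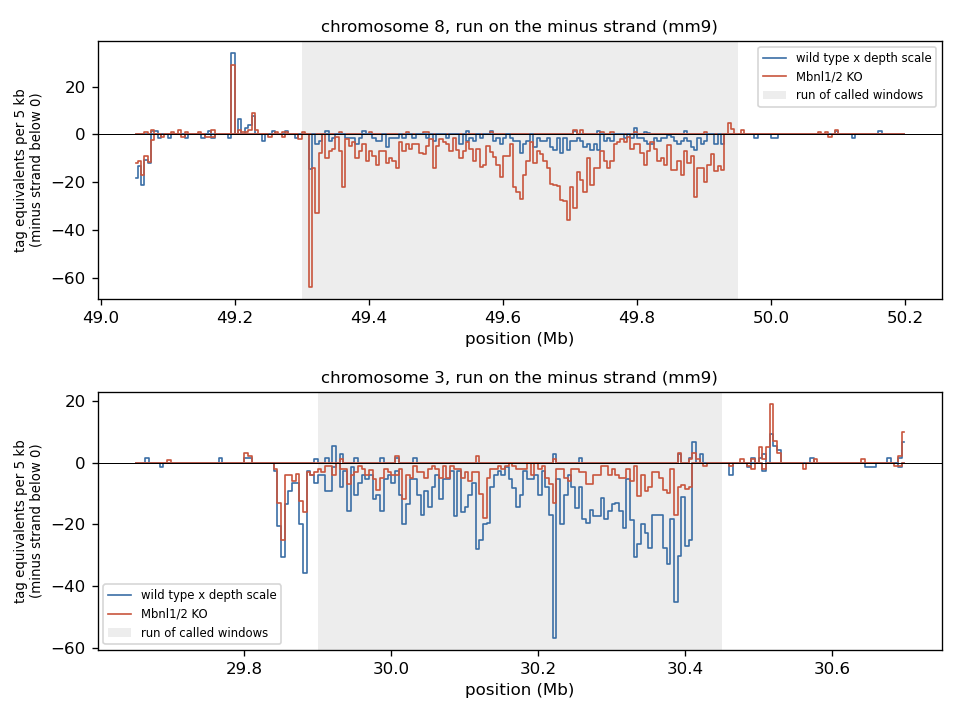
Tag equivalents per 5 kb (y axis, plus strand above and minus strand below 0) along chromosome 8 and chromosome 3 (x axis, Mb, mm9) for wild type multiplied by the depth scale (blue) and Mbnl1/2 KO (red), with 250 kb on either side of the run of called windows (grey). KO coverage exceeds wild type on the minus strand of the chromosome 8 run (ratio 5.58) and falls below it on the minus strand of the chromosome 3 run (ratio 0.32).

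Other runs higher in KO were found on both strands of the genome. On the minus strand of chromosome 16, a run of 250 kb (12600001 to 12850000) rose from 113.0 to 932.2 tag equivalents, a ratio of 6.23 (5.15 to 7.68). It lay in a proximal block of the chromosome where 9 of 10 windows of 1 Mb were higher in KO. Of the 1048.8 KO tag equivalents between 12000001 and 13000000, most lay in this run. On the minus strand of chromosome 15, a run of the same length (26550001 to 26800000) had a ratio of 4.21 (3.40 to 5.31), and on the minus strand of chromosome 14 another (94050001 to 94300000) had 2.69 (2.19 to 3.37). On the plus strand of chromosome 11, 100 kb (96100001 to 96200000) held 33.0 tag equivalents in wild type and 306.6 in KO, a ratio of 6.92 (4.92 to 10.44). The highest ratio of all runs was 8.99 (4.89 to 21.56), from 9.0 and 114.2 tag equivalents on the minus strand of chromosome 10 (102450001 to 102500000), where the opposite strand also went from 2.0 to 22.9. On the plus strand of chromosome 9, a run of 100 kb (47450001 to 47550000) had a ratio of 5.99 (3.69 to 11.19), with 131.0 tag equivalents in KO, while the opposite strand held 15.9 in wild type and 15.0 in KO. The first covered window of the same strand (3000001 to 3050000) had a ratio of 6.69 (3.48 to 17.30) and was raised on both strands, from 8.0 to 75.9 and from 16.9 to 54.0. Many wild-type start positions of these runs were also KO start positions. The numbers were 93 of 104 on chromosome 16, 67 of 87 on chromosome 15, 43 of 97 on chromosome 14 and 29 of 32 on chromosome 11. They were 7 of 8 on chromosome 10, 15 of 15 in the 100 kb on chromosome 9 and 1 of 7 in its first window. The intervals do not cover tags present in both profiles.

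Runs lower in KO included the lowest ratio, 0.08 (0.02 to 0.17), on the minus strand of chromosome 5 (121150001 to 121200000), where 55.0 tag equivalents in wild type stood against 5.0 in KO. The minus strand of chromosome 7 (149750001 to 149800000) held 149.0 and 26.0 tag equivalents, a ratio of 0.14 (0.08 to 0.20), and the minus strand of chromosome 12 (27100001 to 27150000) had a ratio of 0.13 (0.06 to 0.24). On the minus strand of chromosome 2, 100 kb (121500001 to 121600000) fell to 0.15 (0.09 to 0.24) of wild type, and on the plus strand of chromosome 16 a window of 50 kb (97750001 to 97800000) to 0.19 (0.11 to 0.27). A run of 250 kb on the minus strand of chromosome 19 (28400001 to 28650000) had a ratio of 0.43 (0.36 to 0.52). All of these differences exceeded counting error, and with 1 pooled profile per genotype they have no replicate check. Whether the runs, higher or lower, follow the amount of RNA was not tested. KO start positions of the lower runs were in part also wild-type start positions. The numbers were 19 of 22 on chromosome 7, 17 of 25 on chromosome 16 and 54 of 141 on chromosome 19. They were 9 of 19 on chromosome 2, 4 of 8 on chromosome 12 and 2 of 5 on chromosome 5. The intervals do not cover such tags here either.

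The profiles also shared individual start positions. The share was higher on the side with fewer tags in the runs, but the runs were picked for unequal counts, and a share rises by itself on that side. Of 513800 start positions in wild type, 124666 (24.3%) were also start positions in KO. The share was 45.1% (43.8 to 46.4) for wild-type starts in the runs higher in KO. For KO starts it was 36.5% (35.3 to 37.6) in the runs lower in KO, against 19.7% of all KO starts. With shared positions left out, which moves unequal counts further apart by construction, the log2 ratio of the chromosome 8 run went from 2.48 to 4.50. Among isolated positions, where a covered stretch held a single start, 68303 matched exactly, against 374 to 817 at each offset of 1 to 10 nt. No start position carried more than 2 tags in either profile, and 2 tags were found at 13.7% of the positions in wild type and 22.0% in KO.

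**Figure D3:**
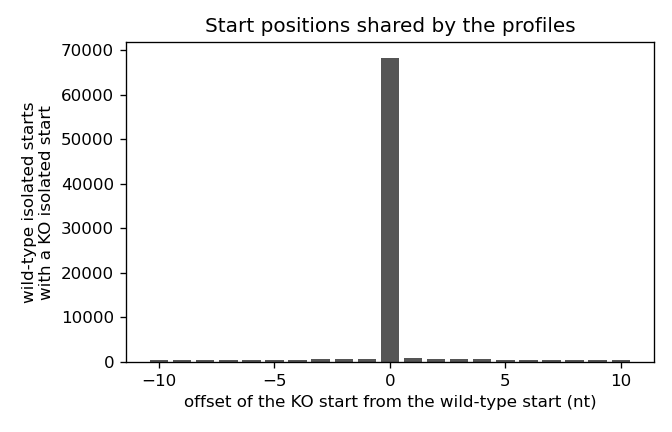
Number of isolated wild-type start positions (y axis) with an isolated KO start position at each offset from -10 to 10 nt (x axis). The bar at offset 0 reaches 68303, and no other bar exceeds 817.

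By chromosome, differences in Mbnl1/2 KO coverage included those of chromosomes 7, 8 and 16. Chromosome 7 held 4.48% of the wild-type coverage and 3.80% of the KO coverage, a ratio of 0.85 (0.84 to 0.86), and 118 of its 143 windows of 1 Mb were lower in KO, against 1258 of 2261 on the other autosomes. Chromosome 16 had a ratio of 1.14 (1.12 to 1.16) and chromosome 8 of 1.13 (1.11 to 1.15). The X chromosome stood at 1.00 (0.98 to 1.02). The Y chromosome, with only 363.7 and 581.9 tag equivalents, stood at 1.21 (1.06 to 1.39), but 2 of its 3 windows of 1 Mb were lower in KO. Sequences assigned to Y without a position (Y_random), with 2082.2 and 2457.5 tag equivalents, went the other way, at 0.90 (0.84 to 0.95). The chromosome 16 difference came mostly from its proximal end. Between 3000001 and 13000000, KO coverage was 1.87-fold (1.80 to 1.96) that of wild type and 9 of 10 windows of 1 Mb were higher, whereas the log2 ratio of the rest of the chromosome was 0.04. Among 247 blocks of 10 such windows, this block had the highest median log2 ratio, 0.85, the next being 0.35 and the lowest -0.42. The mitochondrial genome, with 1000.5 and 1620.2 tag equivalents, had a ratio of 1.23 (1.14 to 1.33).

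**Figure D4:**
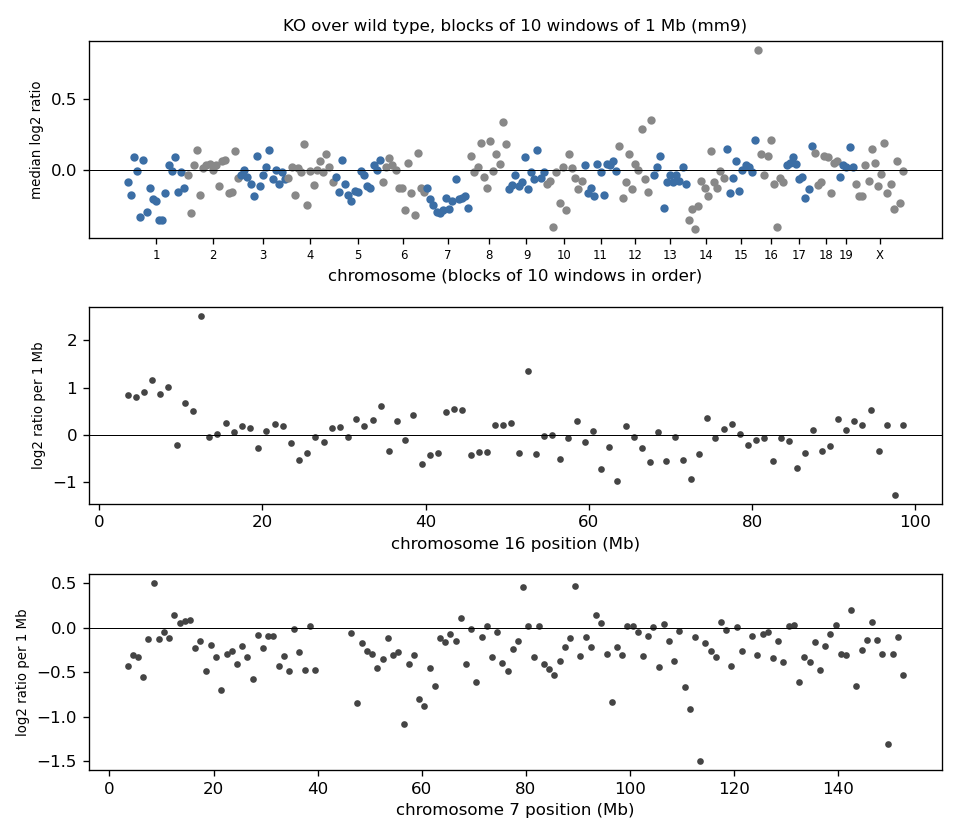
Top, median log2 ratio of Mbnl1/2 KO over wild type (y axis) for blocks of 10 windows of 1 Mb in order along the autosomes and the X chromosome (x axis; the shade alternates by chromosome); middle and below, log2 ratio per window of 1 Mb along chromosomes 16 and 7 (x axis, Mb). The proximal block of chromosome 16 stands at 0.85, above all others, and 118 of 143 windows of chromosome 7 lie below 0.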

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

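No paired analysis was possible because the libraries of each genotype were pooled into 1 profile, and leaving out a replicate could not be run for the same reason. Alternatives set before the data were examined that need mm9 annotation (other gene regions, features, 3′ end windows, 3′ UTR splits, motifs and gene lists) were not run. Alternatives for windows, pairs and chromosomes, island heights of 5 and 20 as a choice of regions, start positions counted once or left out when shared, and islands without the chromosome 8 array were added after the data were seen. For islands, the counts at least 2-fold higher and lower in KO (2 and 25) became 11 and 2 on the median scale, 18 and 76 with a minimum of 20 tags, 0 and 2 with 200, 6 and 126 at 1.5-fold, and 0 and 4 with each start position counted once. The higher count was 0 at an island height of 20, and the lower count was 15 with capped coverage and 16 with a pseudocount of 5. The median log2 ratio of islands (-0.59) is 0 on the median scale by construction. It was -0.39 and -0.52 with minimums of 20 and 200 tags, -0.65 at height 20, -0.45 with starts counted once, -0.75 without shared starts and -0.53 without the chromosome 8 array. Of 132 values of named islands under the alternatives, 99 stayed within the counting interval and 29 moved out of it. The other 4 changed direction, which was counted only for islands whose counting interval excluded 0. These 4 lay on chromosome 17 (39982386), chromosome 6 (3150766), chromosome 19 (5800067) and chromosome 11 (108872956). On the median scale their log2 ratios became 0.19, 0.19, 0.26 and 0.09. Among the 29 that moved, the value of the chromosome 19 island at 5795962 with capped coverage also changed sign. It went from 0.06 (-0.05 to 0.17) to -0.12. The cause was not tested for these changes, beyond the smaller or larger number of regions that a minimum of tags or a fold admits.

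For windows, the counts (310 and 242) became 952 and 741 with a minimum of 20 tags, 20 and 14 with 200, and 1222 and 725 at 1.5-fold; the higher count was 190 with starts counted once and 473 without shared starts. The median log2 ratio of windows (0.12) was 0.15 and 0.11 in windows of 20 and 100 kb, 0.09 with a minimum of 20 tags, 0.10 without strand, 0.10 with starts counted once and 0.16 without shared starts. Leaving out shared starts takes the same positions from both profiles, which by construction moves a ratio away from 1, so that these values, for islands too, neither show stability nor estimate the size of a difference. Of 126 values of named runs under the alternatives, 114 stayed within the counting interval, and the other 12 were all without shared starts. Islands in wild type only and in KO only (269 and 430) numbered 1822 and 4589 at height 5, 63 and 37 at height 20, and 504 and 61 with KO heights scaled down, so that the larger group changed. A minimum of 20 tags gave 145 pairs of islands, 4 of them shifted at least 2-fold, and 29 pairs were left without the chromosome 8 array, 0 of them shifted at least 2-fold. On the median scale of the windows and without shared starts, the log2 ratio was -0.36 and -0.30 on chromosome 7, 0.05 and 0.25 on chromosome 8, 0.06 and 0.25 on chromosome 16, and 0.78 and 1.29 in its proximal block. Depth limits the precision: the ratio of 2.57 from 14.0 and 49.0 tag equivalents had an interval of 1.44 to 5.21.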

Other observations

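The tests of repeated loci, of a few strong regions, of separate transcripts, of sharing within runs, of islands before scaling and of windows thin in wild type were chosen only after the result was seen; all explanations here are hypotheses.

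The exact sharing of start positions between the wild-type and Mbnl1/2 KO profiles was set against 3 explanations. Pile-up in a few repeated loci is argued against, since the 1% of 1-Mb windows with most shared isolated starts held 4.9% of them. Under independent cutting at preferred positions, sharing should nearly vanish at wild-type starts with no other start within 5 kb. It stood at 8.5% there, against 0.46% at a given offset of 1 to 10 nt. This share was lower than the 24.3% of all starts and the 17.76% of isolated starts, the direction such cutting predicts. A sharply preferred position would also give exact matches, so this test does not decide on the explanation. The numbers of tags at shared isolated positions, given in the last paragraph, argue against it as the whole source. Tags spanning 36 nt in wild type met a KO tag of 36 nt at the same start in 90.1% of cases (3526 of 3914), against 7.6% at starts 1 to 10 nt away, a difference of 82.5 percentage points, which is consistent with the same tags being present in libraries of both genotypes. In the runs higher in KO, 45.1% of the wild-type starts were shared (24.3% overall), and in the runs lower in KO, 36.5% of the KO starts (19.7% overall); a share rises by itself where its own side has fewer tags, but if these tags were carried over, the ratios of the runs may lie too close to 1, by an amount that was not estimated. How such tags came to be shared was not tested, and no biological explanation was tested.

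The proximal block of chromosome 16 (3000001 to 13000000) was higher in Mbnl1/2 KO in 9 of 10 windows of 1 Mb, the exception being 9000001 to 10000000 at a log2 ratio of -0.22, with a drop to a median log2 ratio of 0.11 over the next 10 windows. A few strong regions as the whole source are argued against by a log2 ratio of 0.92 (0.84 to 0.99) without the 10 strongest windows of 50 kb, 0.30 above the highest of the other 230 autosomal blocks treated alike. Independent changes of separate transcripts are argued against by shuffling the autosomal windows of 1 Mb, since 0 of 10000 shuffles gave a block median as high as the observed 0.85 (highest 0.54). The shuffle takes windows as exchangeable over the autosomes, although 118 of 143 windows of chromosome 7 were lower in KO. It therefore does not speak against changes that neighbouring transcripts share. Windows with under 20 tags had a log2 ratio of 0.42 in the block and -0.20 on the other autosomes, a difference of 0.62 (0.44 to 0.80, counting interval), which falls short of the 0.92 above. This limit counts KO tags too and so drops windows that a raise lifts over it: of a raise of 0.9 put on the KO tags of the other autosomes, it left 0.80. With windows picked by under 9 wild-type tags instead, which favours windows low in wild type inside and outside the block, the difference was 0.87 (0.72 to 1.03). A gain of copies of this segment in the KO cultures is thus a candidate explanation for at least part of the raise. A regional effect of Mbnl1/2 loss on transcription of neighbouring genes stays open and was not tested. Neither was checked in other libraries of these MEFs, which were not analysed here.

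Strong islands were lower in Mbnl1/2 KO relative to total coverage. The limit of 2 tags per start position is argued against as the whole source: 171 of the 247 islands had fewer tag equivalents in the deeper KO profile even before scaling, the median share of filled start positions was 24.2% in wild type and 20.2% in KO, and a correction for filled positions, which assumes that tags fill an island evenly, took the median log2 ratio from -0.59 to -0.64, a change of -8.0% of its size counted towards 0. More scattered single tags in KO were not seen. With KO thinned to the wild-type number, 52.5% of KO tags had no other tag within 50 nt, against 55.8% in wild type, a difference of -3.3 percentage points. Double tags in KO widen this difference, but by start position KO was not higher either, at 71.4% (71.2 to 71.5) against 71.8% (71.7 to 71.9). These shares cannot exclude the explanation. Stretches reaching a height of 10 held only 5.3% of the wild-type and 4.2% of the KO coverage. Nearly all coverage lay outside them. A clear rise of it relative to the islands would therefore change the shares of tags or starts with no other within 50 nt only slightly. An effect of Mbnl1/2 loss on CPSF6 at these loci, and a difference between preparations in how much of these RNAs was recovered, stay open and were not tested.

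Tags spanning 36 or 37 nt made up 11.43% (11.32 to 11.53) of isolated single tags in wild type and 10.06% (9.97 to 10.16) in KO, against 87.73% and 89.11% spanning 35 nt. Isolated positions shared with wild type carried 2 tags in KO in 24612 of 68303 cases, against 69813 of 386044 for KO positions that were not shared. In wild type the numbers were 7150 of 68303 and 37872 of 316384. Independent cutting at preferred positions predicts 2 tags more often at shared positions in both profiles. The KO numbers went that way, but in wild type 2 tags were less frequent at shared positions. For isolated positions, this argues against such cutting as the whole source of the sharing.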
